A study of Mus musculus with 9 samples.

How the data were processed

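The data are messenger RNA sequencing of mouse tumor tissue in 9 libraries, 3 per group. The groups are tumors given PBS (the vehicle), tumors given circRNA, and tumors given circRNA together with an antibody against PD-1. Libraries are named here by group and replicate number as in the labels (PBS 1, circRNA 2), and the third group is called the combination. Per the labels' protocols, total RNA was extracted with a column kit that includes DNase digestion, messenger RNA was captured with oligo-dT beads, stranded libraries were prepared, and paired ends were read on a NextSeq 2000. The labels give neither the tumor line, the dose nor the day of collection, and they do not say whether the 3 libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

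The authors deposited a table of whole-number counts of read pairs per gene name. Per the file header, featureCounts 2.0.3 counted fragments with both ends mapped over the exons of each gene name, with the setting for reversely stranded libraries (2), on the GENCODE vM30 annotation of mouse assembly mm39. Alignment was with STAR 2.7.9a, and FastQC and Subread 2.0.3 are also listed, per the submitters' processing notes. The header names trimmed reads, and the trimming tool is not given in the sources used here. The header's options do not include counting of fragments that map to several places, so counts of genes with near-identical copies are uncertain. A second deposited table of counts holds 20551 of the 55809 genes. It differs from the full table in 0 cells, its lowest gene sum over the libraries is 10, and the highest sum among the genes left out of it is 9. Each count column carries the label of 1 sample, 9 columns in all, and 0 columns were left unused.

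Library totals ran from 19712911 to 27169243 counted fragments. All 9 libraries were compared pairwise within groups before averaging. A chi-square per gene of 15.3 to 38.6 showed that no pair differed by as little as sampling noise, so each library counted as 1 replicate.

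Differential expression was tested from the counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 15132 genes holding at least 99.4% of the counts of each library. TMM factors lay between 0.97 and 1.02. A quasi-likelihood model with 1 coefficient per group was fitted to all 9 libraries, with 6 residual degrees of freedom, and each of the 3 comparisons was tested with the quasi-likelihood F test and Benjamini-Hochberg adjustment. The common dispersion was 0.0279, a biological coefficient of variation of 0.167. A gene was called at an adjusted p below 0.05 with no minimum fold. CPM values are edgeR's, with TMM-normalized library sizes, and are given as mean ± SD over 3 libraries, and log2 fold changes are given with the standard error (SE) that the F statistic implies, the size of the log2 fold change divided by the square root of F.

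Before the data were examined, 28 gene lists for cell types and pathways were written down, 561 genes in all with 9 genes in more than 1 list. They cover T cells, cytotoxic effectors, NK cells, checkpoints, regulatory T cells, the type I interferon response, the interferon gamma response, MHC class I, MHC class II, RNA sensing, inflammatory cytokines, dendritic cells, macrophages and monocytes, neutrophils, B and plasma cells, fibroblasts and matrix, endothelium, melanocytic cells, epithelial cells, keratinocytes, skeletal muscle, adipocytes, erythroid cells, cell cycle, p53 response, hypoxia and glycolysis, immediate early and heat shock genes, and mitochondrial transcripts. Each list was tested with camera from limma 3.58.1, which asks whether a list moves more than other genes, with a preset inter-gene correlation of 0.01. The adjustment ran over the 27 lists with at least 5 genes past the filter. Camera with a correlation estimated for each list was run beside it, and so was fry. The fry p-value tests whether the genes of a list move one way on balance, its mixed p-value tests whether they change in either direction, and neither compares the list with other genes. A list score is the mean over its genes of log2 CPM (prior count 2) centred on the mean of the 9 libraries. Counts of list members called were also adjusted over the list alone.

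Genes to be named were chosen by a rule fixed at the same time. Where no gene was called, the rule takes the 5 genes with the smallest p in each direction whose 3 libraries lie apart from the other 3 and whose mean CPM reaches 5 in the higher group. To these it adds the 2 members with the smallest p of each list that was called, and a fixed panel of Pdcd1, Cd274, Cd8a, Gzmb, Ifng, Cxcl9, Isg15, Ddx58, Ifih1 and Eif2ak2. Predicted genes, pseudogenes and variable segments of antigen receptors were left out of the naming, and the receptor segments were only counted.

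The pipeline was tested on simulated counts drawn from the real means, library sizes and dispersions over 15132 genes. For circRNA against PBS, edgeR recovered 68% of genes changed 2-fold and 88% of those changed 4-fold, with 8.14% false calls, against 76% and 90% with 20.4% false calls for DESeq2. For the combination against PBS, edgeR recovered 77% and 94% with 5.46% false calls, and DESeq2 82% and 94% with 18.2%. For the combination against circRNA, edgeR recovered 68% and 84% with 7.19% false calls, and DESeq2 75% and 85% with 22.3%. A T cell list raised 1.5-fold was called in all 3 simulated comparisons, while 1, 0 and 0 of the other lists were called. The simulated genes were drawn independently of each other. In the real data the estimated correlation of the T cell list was 0.769 in circRNA against PBS. The simulation therefore cannot show how often lists of genes that move together are falsely called. For single genes, the recovered shares hold for independent genes with 100 changed 2-fold and 100 changed 4-fold. They do not show that few genes changed where edgeR called 0. In the real circRNA against PBS, Fgr was not called at a fold of 2.07 (edgeR adjusted p = 0.192).

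Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scaling factors, no filter, a stricter filter of 1 CPM on average, the authors' shorter count table, the compared groups alone, the replicate number as a block, a robust spread, a fold threshold of 1.5, and each library left out in turn. The filter was applied anew when libraries were left out. With 1 library left out the smallest group held 2 libraries, and 15347 to 15972 genes passed. List medians there can therefore cover other genes than the main ones. Other splits of the libraries, the likelihood ratio test and exact permutation tests of the list scores are given with the closing observations. Principal components were computed on log2 CPM of the 1000 most variable genes. Chance values for results that share the PBS libraries were taken from 20 simulations with no change in either treated group, for edgeR also with circRNA 2 and combination 1 left out. Exact 95% Poisson intervals on receptor segments cover counting error only.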

Results

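Tumor tissue from mice was profiled by messenger RNA sequencing to ask how vaccination with small circular RNA (circRNA), alone or with an antibody that blocks the inhibitory receptor PD-1, is reflected in the transcriptome of the tumor. PBS, the vehicle, served as the control. Each of the 3 groups had 3 libraries. Counted fragments were 24779478, 25256824 and 19712911 in PBS 1, 2 and 3, 21854388, 25542050 and 22269162 in circRNA 1, 2 and 3, and 27169243, 25462042 and 25694038 in the combination libraries 1, 2 and 3. Expression was measured for 15132 genes. The design holds no tumors given the antibody alone, so its effect can be read only on top of circRNA.

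The libraries of a group resembled each other no more than those of different groups. The correlation of log2 CPM across genes, which are not independent replicates, averaged 0.984 within groups (9 pairs, 0.975 to 0.991) and 0.983 between groups (27 pairs, 0.962 to 0.992). The first principal component held 52.6% of the variance and set apart circRNA 2 and combination 1. Its leading genes were keratinocyte genes such as Krt5, Perp and Lgals7. Krt14, a keratin of the basal epidermis, stood at 513 CPM in circRNA 2 and 364 CPM in combination 1, against at most 2.02 CPM in the other libraries. Krt10, a keratin of the upper epidermis, stood at 536 and 646 CPM, against at most 5.81 CPM. The fat cell gene Cfd reached 14.9 CPM in circRNA 2, 11.3 CPM in combination 1 and 6 CPM in PBS 1. The same libraries therefore appear beside the immune gene groups that follow, as measured values.

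circRNA alone was compared with PBS to ask which tumor transcripts go with the vaccine. Transcripts of T cells, cytotoxic lymphocytes, antigen-presenting myeloid cells and interferon gamma targets were higher in the circRNA tumors, and those of hypoxia and glycolysis were lower, as lists called by camera with a preset correlation. None of the lists held with an estimated one (lowest adjusted p = 0.234 with an estimated correlation). The T cell list rose by a median log2 fold change of 1.22, with 21 of 22 genes higher (adjusted p = 0.234 with an estimated correlation). Its score was above every PBS library in each of the 3 circRNA libraries (0.412 ± 0.51 against -0.624 ± 0.11, SD, n = 3). The interferon gamma list rose by a median of 0.67 with 27 of 27 genes higher, and the hypoxia list fell by a median of 0.4 with 21 of 23 genes lower. Both had adjusted p = 0.234 with an estimated correlation. No single gene passed the test: edgeR called 0 of 15132 genes (lowest adjusted p = 0.192), with 2244 genes at an unadjusted p below 0.05 where 757 are expected by chance for independent genes. Splits of the same 6 libraries that mix the groups gave up to 1826. Without circRNA 2 there were 994 such genes, and 1057 without combination 1 as well. limma-voom called 0, and DESeq2 called 360, of which 289 were higher and 71 lower, 262 of the higher ones with their highest circRNA value in circRNA 2. For 347 of the 360 the 3 circRNA libraries lay apart from the 3 PBS libraries, which selection by a test on the same libraries favors.

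**Figure D1:**
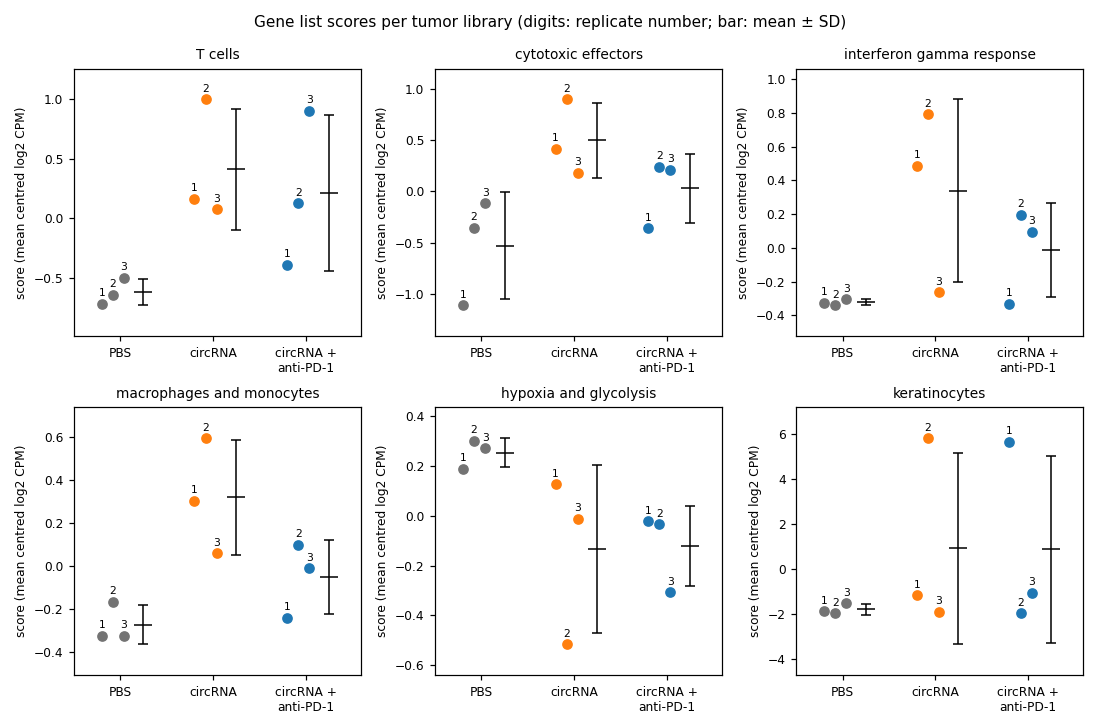
Scores of 6 gene lists in each library (mean log2 CPM of the list's genes, centred on the 9 libraries), by group, with points numbered by replicate and bars for the mean ± SD. The 3 circRNA libraries lie above the 3 PBS libraries for T cells (0.0755 to 0.999 against -0.72 to -0.504), and circRNA 2 and combination 1 stand apart for keratinocytes at 5.81 and 5.66.

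Among the lymphocyte lists in this comparison, the camera test called T cells (adjusted p = 5.41e-14) and cytotoxic effectors (median 1.06, 21 of 21 higher, adjusted p = 2.99e-12), both with adjusted p = 0.234 with an estimated correlation. It also called NK cells (0.85, 15 of 15 higher, adjusted p = 4.21e-07), checkpoints (0.79, 14 of 16 higher, adjusted p = 3.71e-08) and regulatory T cells (0.51, 10 of 10 higher, adjusted p = 1e-04). Each of these also had adjusted p = 0.234 with an estimated correlation. Over all genes edgeR called 0 of their members, and adjusted over the list alone 18 T cell, 11 cytotoxic, 5 NK cell, 10 checkpoint and 5 regulatory T cell genes. DESeq2 called 6, 6, 3, 2 and 1 of them over all genes. Zap70, which signals from the T cell receptor, was at 5.21 ± 1.54 CPM against 2.23 ± 0.281 in PBS (SD, n = 3). Cd8b1 and Nkg7, genes of cytotoxic lymphocytes, had log2 fold changes of 1.78 ± 0.45 and 1.21 ± 0.32 (SE). The NK cell list was led by Styk1 (0.92 ± 0.2) and the chemokine gene Xcl1 (1.12 ± 0.26). Pdcd1lg2, a ligand of PD-1, was at 19.5 ± 15.5 against 2.84 ± 1.27 CPM and Cd160 at 1.26 ± 0.282 against 0.461 ± 0.172. The regulatory T cell genes Ikzf4 and Tnfrsf18 had log2 fold changes of 1.33 ± 0.39 and 1.04 ± 0.29 (edgeR adjusted p = 0.198 to 0.214 for the genes of this paragraph). circRNA 2, which carried the keratinocyte transcripts, had the highest score of the 9 libraries in each of these 5 lists. Without it the T cell median was 0.77 and the NK cell median 0.46, and without PBS 1 the NK cell median was 0.5.

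Antigen presentation and myeloid lists were also higher. As lists, MHC class II, which presents antigen to helper T cells (median 0.75, 11 of 11 genes higher, adjusted p = 2.3e-12), and macrophages and monocytes (0.44, 22 of 24 higher, adjusted p = 8.08e-15) rose, both with adjusted p = 0.234 with an estimated correlation. The dendritic cell list (0.58, 16 of 18 higher, adjusted p = 2.95e-06) and the inflammatory cytokine list (0.56, 24 of 26 higher, adjusted p = 2.03e-10) rose, both with adjusted p = 0.234 with an estimated correlation. So did the neutrophil list (1.26, 10 of 11 higher, adjusted p = 0.000159) and the interferon gamma list (27 of 27 higher, adjusted p = 5.53e-17), both again with adjusted p = 0.234 with an estimated correlation. MHC class I rose by a median of 0.12 (17 of 21 higher, adjusted p = 0.000319) and RNA sensing by 0.11 (23 of 27 higher, adjusted p = 0.000233), both with adjusted p = 0.388 with an estimated correlation. Adjusted over the list alone, 8 MHC class II, 17 macrophage, 8 dendritic cell, 11 cytokine, 7 neutrophil, 12 interferon gamma, 4 MHC class I and 4 RNA sensing genes passed, against 0 over all genes by edgeR. DESeq2 called 5, 5, 4, 6, 2, 7, 3 and 3 of them over all genes, in the same order. Ciita, the master regulator of MHC class II, was at 70.6 ± 25.4 CPM against 30.6 ± 8.39 (log2 fold change 1.21 ± 0.28) and H2-DMa at 142 ± 30.9 against 85 ± 16.4. The monocyte receptor gene Ccr2 was at 130 ± 24.7 against 69.4 ± 8.19 CPM and the integrin gene Itgam at 77.3 ± 10.8 against 49.4 ± 3.01. The chemokine gene Ccl22 was at 10.4 ± 1.47 against 3.94 ± 0.99 and Cd40 at 22.7 ± 5.85 against 11.6 ± 1.74. Tnf was at 8.64 ± 1.52 against 5.06 ± 0.713 CPM and Ccl2, which attracts monocytes, at 342 ± 38 against 233 ± 20.6. In the smaller shifts, Irf5 and the endosomal RNA receptor gene Tlr13 had log2 fold changes of 0.54 ± 0.13 and 0.41 ± 0.09, and H2-T24 and Tapbpl 0.75 ± 0.2 and 0.34 ± 0.09. The neutrophil list was led by Clec4e (1.3 ± 0.37) and Clec4d (1.51 ± 0.49), and edgeR gave adjusted p = 0.198 to 0.233 for the genes of this paragraph. circRNA 2 had the highest score of the 9 libraries in each list of this paragraph other than MHC class I, and the neutrophil score of circRNA 3 (-0.532) lay below every PBS library. Without circRNA 2 the neutrophil and dendritic cell medians were 0.77 and 0.38. The RNA sensing median was 0.062 without circRNA 1 and 0.17 without circRNA 3. The MHC class I call ended without PBS 1 (median 0.09, adjusted p = 0.0713).

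The lists that fell in circRNA against PBS were hypoxia and glycolysis (adjusted p = 8.37e-10, adjusted p = 0.234 with an estimated correlation) and fibroblasts and matrix (median -0.44, 15 of 23 lower, adjusted p = 0.00111, adjusted p = 0.383 with an estimated correlation). Mitochondrial transcripts fell too (-0.21, 10 of 10 lower, adjusted p = 0.00735, adjusted p = 0.396 with an estimated correlation). Adjusted over the list alone, 0 hypoxia, 6 fibroblast and 0 mitochondrial genes passed, against 0 over all genes by edgeR and 1, 5 and 0 by DESeq2. Ndrg1, a hypoxia-induced gene, was at 338 ± 92 CPM against 554 ± 77.7 (log2 fold change -0.71 ± 0.18, edgeR adjusted p = 0.198). Pfkfb4, which codes for a regulator of glycolysis, went against its list at 31.6 ± 1.8 against 25 ± 1.89. The collagen gene Col6a2 was at 1030 ± 263 against 1820 ± 465 CPM. Thy1, which T cells of the mouse also express, went against the fibroblast list at 45.6 ± 14.8 against 25 ± 1.75. mt-Co3 and mt-Atp6 had log2 fold changes of -0.45 ± 0.25 and -0.35 ± 0.18 (edgeR adjusted p = 0.431 and 0.402). Both had few counts, at 2.24 ± 0.383 against 3.07 ± 0.479 CPM and 2.64 ± 0.191 against 3.37 ± 0.244 CPM, while mt-Co1 was at 4430 ± 605 CPM in PBS. Fragments that map to several places were not counted, so these values need not mean low expression. Without circRNA 2 the hypoxia median was -0.2. The fibroblast call ended without PBS 3 (-0.27, adjusted p = 0.0814) and its median was -0.68 without circRNA 1. The mitochondrial call ended without PBS 3 (-0.066, adjusted p = 0.311) and without circRNA 3 (-0.13, adjusted p = 0.0965).

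The keratinocyte list was called (median 6.42, 8 of 8 higher, adjusted p = 0.0144, adjusted p = 0.495 with an estimated correlation). Krt14 was at 172 ± 295 CPM against 0.922 ± 0.357 and Krt5 at 82.1 ± 141 against 0.0272 ± 0.0472 (edgeR adjusted p = 0.285 and 0.29), and 0 genes passed adjusted over the list alone. That call rested on circRNA 2, without which the median was 0.28 (adjusted p = 0.896). Leaving out any of the libraries PBS 1, PBS 2, PBS 3, circRNA 1, circRNA 3, combination 2 or combination 3 gave medians of 9.76 to 10.7. The filter passed more genes there, so these medians are over another set of genes. The type I interferon response had a median of 0.13 with 27 of 37 higher, and medians of -0.00088 to 0.23 with 1 library left out. It passed without PBS 2 (adjusted p = 0.0122), PBS 3 (0.011), circRNA 2 (0.00473), circRNA 3 (3.94e-06) or combination 1 (0.0418). With all libraries it was not called (adjusted p = 0.0542). Nor were B and plasma cells (median 0.22, adjusted p = 0.354), endothelium (0.063, 0.354), melanocytic cells (0.44, 0.0852), epithelial cells (1.57, 0.0542), adipocytes (1.2, 0.403) or erythroid cells (-0.51, 0.112). The same held for cell cycle (0.022, 0.593), p53 response (0.054, 0.406) and immediate early and heat shock genes (0.064, 0.403). The epithelial list was called without each single library other than circRNA 2 (medians 1.55 to 4.12 over the genes then kept). Without circRNA 2 its median was -0.33. Also called were endothelium without circRNA 3 (0.12, adjusted p = 0.0145), melanocytic cells without PBS 3 (0.64, 0.0301) or circRNA 3 (0.75, 0.024), and adipocytes without PBS 1 (5.54, 0.0259). The adipocyte median ran from -4.14 to 5.54 with 1 library left out. Erythroid cells were called lower without PBS 1 (-0.91, 0.00722) or circRNA 1 (-0.92, 0.035). Skeletal muscle had 4 genes past the filter, with a median of 0.78, and was not tested. Of these lists, adjusted over the list alone, 1 B and plasma cell, 2 epithelial, 1 p53 and 3 immediate early genes passed, and 0 of the type I interferon, endothelium, melanocytic, adipocyte, erythroid, cell cycle and skeletal muscle genes.

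**Figure D2:**
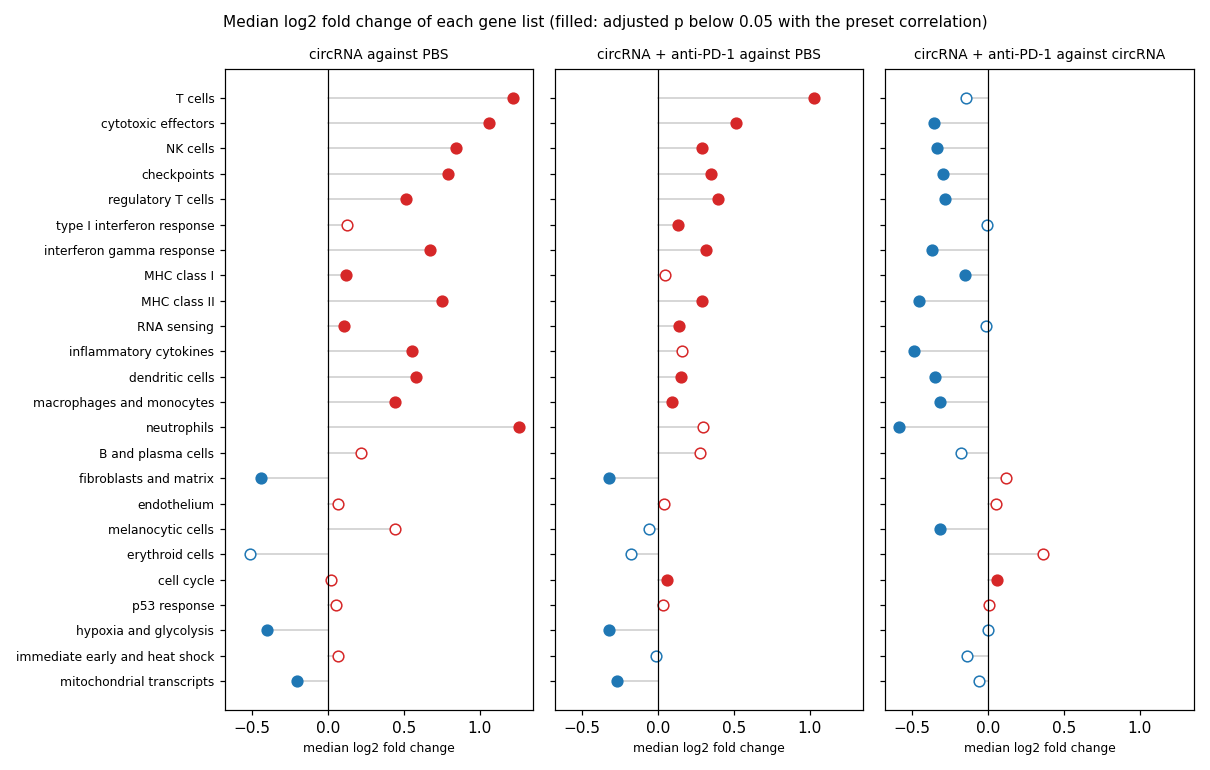
Median log2 fold change of the genes of each list in the 3 comparisons, with filled points for lists called by camera with the preset correlation and open points for the rest (the epithelial, keratinocyte, skeletal muscle and adipocyte lists, with medians up to 6.42, are not drawn). T cells stand at 1.22 and 1.03 against PBS and at -0.15 between the treated groups.

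Outside the lists, the gene with the smallest p in circRNA against PBS was Fgr. Fgr, a Src family kinase of myeloid cells (chromosome 4, 132701406 to 132729221 on mm39), was at 38 ± 5.59 CPM against 18.4 ± 0.953 (SD, n = 3), a log2 fold change of 1.05 ± 0.13 with an edgeR adjusted p = 0.192. With the filter on low counts lifted, Fgr was the only gene that edgeR called (adjusted p = 0.0425). Gna15 (chromosome 10, 81338140 to 81360059), Dpep2 (chromosome 8, 106711576 to 106723055), Pilra (chromosome 5, 137820214 to 137834543) and Adgre5 (chromosome 8, 84449880 to 84467955) had log2 fold changes of 0.83 ± 0.13, 0.66 ± 0.12, 0.59 ± 0.11 and 0.94 ± 0.17. On the lower side stood Fbxo25 (-0.51 ± 0.1), Slc49a4 (-0.4 ± 0.08), Lbx1 (-0.47 ± 0.1), Hbp1 (-0.42 ± 0.09) and Klhl24 (-0.58 ± 0.12), all with an edgeR adjusted p = 0.198, as had the higher genes after Fgr. In the fixed panel, Cd8a was at 15.7 ± 5.61 CPM against 5.62 ± 0.78, and Pdcd1 at 7.34 ± 2.76 against 3.2 ± 0.773. Cd274, which codes for PD-L1, was at 149 ± 71.4 against 67.9 ± 2.24 and Cxcl9 at 423 ± 168 against 192 ± 27.4, and for these 4 genes the 3 circRNA libraries lay above the 3 PBS libraries. The groups overlapped for Gzmb (72.7 ± 18.4 against 47.3 ± 22.8), Ifng (4.54 ± 3.18 against 1.48 ± 0.512) and the interferon-induced gene Isg15 (100 ± 34.6 against 111 ± 16.6). They also overlapped for the RNA sensors Ddx58 (166 ± 35.8 against 198 ± 35.1), Ifih1 (61.7 ± 12.4 against 61.7 ± 10.6) and Eif2ak2 (70.7 ± 10.2 against 73.3 ± 10.7). None of the 10 passed (edgeR adjusted p = 0.198 to 0.998). Over all genes, 1342 had every circRNA library above every PBS library and 1230 below, 17% together where chance gives 10%.

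Limits of this comparison are that fry called 0 lists (lowest adjusted p = 0.131, mixed 0.0678) beside the 17 that camera called, and that genes of similar families such as H2-T24 have uncertain counts. With circRNA 2 and combination 1 left out, an alternative chosen after seeing the data, edgeR called 0 genes, while the T cell and cytotoxic lists were still called (medians 0.77 and 0.81, adjusted p = 0.246 and adjusted p = 0.176 with an estimated correlation); with PBS 1 left out as well, their medians were 0.79 and 0.52, that of NK cells 0.097, MHC class II 0.41 and macrophages 0.21, and the MHC class I (adjusted p = 0.14) and RNA sensing (adjusted p = 0.0539) calls ended.

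The combination was compared with PBS to ask what vaccine and antibody do together. T cell transcripts were again higher, with a median log2 fold change of 1.03 and 21 of 22 genes higher, and hypoxia transcripts were lower, with a median of -0.32 and 21 of 23 genes lower. Smaller rises were called for cytotoxic, NK cell, checkpoint, regulatory T cell, interferon and MHC class II lists, with adjusted p = 0.496 to 0.602 with an estimated correlation, as for the T cell and hypoxia lists (0.496). The T cell score was 0.212 ± 0.653 against -0.624 ± 0.11 in PBS (SD, n = 3). All 3 combination libraries were above all PBS libraries, with combination 3 highest at 0.904. edgeR called 0 genes (lowest adjusted p = 0.863), with 749 at an unadjusted p below 0.05 where 757 are expected and mixed splits gave up to 1670. That number was 1426 without PBS 1, 465 without PBS 2 and 338 without combination 3. limma-voom called 0, and DESeq2 called 2, Ccl2 higher and Sema3c lower.

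Against PBS, camera called T cells (adjusted p = 1.06e-17) and cytotoxic effectors (median 0.51, 16 of 21 higher, adjusted p = 5.17e-07), both with adjusted p = 0.496 with an estimated correlation. NK cells (0.29, 11 of 15, adjusted p = 0.00185), checkpoints (0.35, 15 of 16, adjusted p = 3.98e-05) and regulatory T cells (0.4, 8 of 10, adjusted p = 0.00327) were called as well, each with adjusted p = 0.496 with an estimated correlation. So were the interferon gamma response (0.32, 26 of 27, adjusted p = 2.31e-07), MHC class II (0.29, 11 of 11, adjusted p = 0.000299) and RNA sensing (0.14, 22 of 27, adjusted p = 0.000299), each again with adjusted p = 0.496 with an estimated correlation. Dendritic cells (0.15, 16 of 18, adjusted p = 0.0211) and macrophages and monocytes (0.094, 17 of 24, adjusted p = 0.00624) had adjusted p = 0.496 with an estimated correlation. The type I interferon response (0.13, 30 of 37, adjusted p = 0.00168) had adjusted p = 0.602 with an estimated correlation. Adjusted over the list alone, 12 T cell genes passed and 0 genes of the other lists named here, and over all genes 0 passed by edgeR or DESeq2. Lat, an adaptor of the T cell receptor, was at 3.18 ± 1.67 CPM against 1.24 ± 0.0621 and Zap70 at 4.44 ± 1.73 against 2.23 ± 0.281. Cd8a and Cd8b1 had log2 fold changes of 1.51 ± 0.41 and 1.57 ± 0.45. Pdcd1 was at 8.39 ± 5.01 against 3.2 ± 0.773 CPM and Tigit at 3.18 ± 1.84 against 1.23 ± 0.552. Foxp3, the regulator of regulatory T cells, was at 1.19 ± 0.465 against 0.616 ± 0.0816 and Il2ra at 9.65 ± 1.17 against 7.13 ± 1.8. Xcl1 and Styk1 had log2 fold changes of 0.97 ± 0.26 and 0.61 ± 0.2, and Cxcl9 and Ciita 0.7 ± 0.26 and 0.66 ± 0.28. For the interferon-induced genes Slfn5 and Oas3 they were 0.49 ± 0.22 and 0.39 ± 0.2, and for Myd88 and Irf5 of RNA sensing 0.19 ± 0.07 and 0.27 ± 0.13. H2-DMa stood at 0.3 ± 0.18, and of the dendritic cell genes Naaa at 0.36 ± 0.17 and Cacnb3, against its list, at -0.33 ± 0.15. Ly6c2, a monocyte gene, was at 19.1 ± 10.6 CPM against 6.81 ± 1.32 and Ccr2 at 102 ± 19.7 against 69.4 ± 8.19, the genes of this paragraph all having an edgeR adjusted p = 0.863.

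Most of these smaller calls depended on single libraries. Without PBS 1, 8 of the 16 calls ended, among them cytotoxic effectors (0.4, adjusted p = 0.554), NK cells (0.047, 0.769) and regulatory T cells (0.41, 0.18). The others were the type I interferon response (0.061, 0.44), MHC class II (0.099, 0.413), RNA sensing (0.089, 0.0842), dendritic cells (0.23, 0.144) and macrophages (0.0017, 0.877). Without combination 2, the calls of NK cells (0.15, 0.129), type I interferon (0.019, 0.647), MHC class II (0.21, 0.0923), dendritic cells (0.11, 0.487) and macrophages (0.075, 0.256) ended. The checkpoint and interferon gamma medians without it were 0.22 and 0.21. Without combination 3 the T cell median was 0.57, still called. The calls of regulatory T cells (-0.0098, 0.178), dendritic cells (0.15, 0.116) and macrophages (0.023, 0.159) ended without it, with RNA sensing at 0.08. Without PBS 3 the calls of regulatory T cells (0.28, 0.174) and dendritic cells (0.15, 0.298) ended and the NK cell median was 0.58. Without PBS 2 the NK cell and macrophage medians were 0.47 and 0.18. Combination 1, which carried keratinocyte transcripts, had the lowest T cell score of its group at -0.394, and without it the NK cell, dendritic cell and macrophage medians were 0.51, 0.28 and 0.17.

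The lists that fell in the combination against PBS were hypoxia and glycolysis (adjusted p = 3.43e-17) and fibroblasts and matrix (median -0.32, 20 of 23 lower, adjusted p = 0.00219), both with adjusted p = 0.496 with an estimated correlation. Mitochondrial transcripts fell as well (-0.27, 10 of 10 lower, adjusted p = 6.44e-06), likewise with adjusted p = 0.496 with an estimated correlation. Keratinocytes (6.26, 8 of 8 higher, adjusted p = 0.000964) and cell cycle genes (0.061, 25 of 28 higher, adjusted p = 0.00168) were called higher, also with adjusted p = 0.496 with an estimated correlation. Adjusted over the list alone, 1 hypoxia gene passed and 0 genes of the other 4 lists, against 0 over all genes by edgeR or DESeq2. Egln3, an oxygen sensor that hypoxia induces, was at 92.8 ± 5.96 CPM against 136 ± 20 and Ndrg1 at 383 ± 26.1 against 554 ± 77.7. Of the 23 hypoxia genes, 18 had every combination library below every PBS library. Chance gives 10% per gene for both directions together. These genes move together (estimated correlation 0.571), so that share does not measure how likely a count of 18 is. The matrix gene Loxl1 had a log2 fold change of -0.66 ± 0.23 while Thy1 stood at 0.53 ± 0.21. mt-Co1 was at 3660 ± 78 against 4430 ± 605 CPM and mt-Nd6 at 1.65 ± 0.34 against 3.03 ± 1.53, while the replication genes Mcm4 and Mcm2 had log2 fold changes of 0.3 ± 0.11 and 0.27 ± 0.12. Krt5 and Perp were at 92.9 ± 160 and 40.3 ± 69.3 CPM in the combination. Without combination 1 the keratinocyte call ended (1.08, adjusted p = 0.269), while it stood at 9.6 without combination 3. Without PBS 3 the fibroblast (-0.11, adjusted p = 0.459) and cell cycle (0.0012, adjusted p = 0.332) calls ended and the mitochondrial median was -0.14. Without combination 3 the cell cycle call ended (0.027, adjusted p = 0.36) and the fibroblast median was -0.16. The cell cycle median was also 0.094 without PBS 1 and 0.036 without PBS 2.

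Not called in the combination against PBS were MHC class I (median 0.048, adjusted p = 0.555), inflammatory cytokines (0.16, 0.0791), neutrophils (0.29, 0.0614), B and plasma cells (0.28, 0.501), endothelium (0.04, 0.563) and melanocytic cells (-0.058, 0.752). Nor were epithelial cells (0.99, 0.0766), adipocytes (0.99, 0.331), erythroid cells (-0.18, 0.134), p53 response (0.035, 0.2) or immediate early genes (-0.013, 0.555), and skeletal muscle had a median of 0.099. Adjusted over the list alone, 1 cytokine and 2 immediate early genes passed and 0 genes of the other lists of this paragraph. The epithelial list was called without each single library other than combination 1 (medians 0.998 to 3.7), inflammatory cytokines without combination 1 (0.21, adjusted p = 0.00101), and neutrophils without circRNA 2 (0.3, 0.0264) or circRNA 3 (0.34, 0.0322). Adipocytes were called without PBS 1 (5.98, 0.00885), combination 2 (2.1, 0.0217) or combination 3 (2.14, 0.00213), and erythroid cells lower without PBS 1 (-0.36, 0.00885) or combination 1 (-1.44, 0.000159). With 1 library left out, over the genes then kept, medians ran from -2.35 to 5.98 for adipocytes and from -1.44 to 0.39 for erythroid cells.

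The genes with the smallest p in this comparison were Ccl2 (chromosome 11, 81926397 to 81928279), at 344 ± 30.1 CPM against 233 ± 20.6, and Sema3c, at 44 ± 3.95 against 68.4 ± 7.86 (edgeR adjusted p = 0.863, DESeq2 adjusted p = 0.00397 for both). Sema3c (chromosome 5, 17779279 to 17935266) codes for a secreted semaphorin. Gna15, Exo1, Ikzf1 and Fgr followed on the higher side with log2 fold changes of 0.53 ± 0.13, 0.43 ± 0.11, 0.45 ± 0.11 and 0.51 ± 0.13. Igfbp4, Egln3, Pf4 and Pfn2 stood on the lower side with -0.47 ± 0.11, -0.55 ± 0.13, -0.86 ± 0.2 and -0.36 ± 0.09. In the panel, the groups overlapped for Cd274 (84.1 ± 20 against 67.9 ± 2.24 CPM), Gzmb (48.2 ± 6.46 against 47.3 ± 22.8), Ifng (2.18 ± 0.588 against 1.48 ± 0.512) and Isg15 (109 ± 22.7 against 111 ± 16.6). They overlapped too for Ddx58 (206 ± 23 against 198 ± 35.1), Ifih1 (70.3 ± 5.4 against 61.7 ± 10.6) and Eif2ak2 (82.5 ± 4.28 against 73.3 ± 10.7), while Cd8a, Pdcd1 and Cxcl9, given above, did not overlap. Of all genes 727 had every combination library above every PBS library and 813 below, 10.2% where chance gives 10%. fry called 0 lists (lowest adjusted p = 0.568, mixed 0.493). With circRNA 2 and combination 1 left out, chosen after seeing the data, edgeR called 1 gene, Ly6c2 (log2 fold change 1.89, adjusted p = 0.00719).

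The combination was then compared with circRNA alone to ask what the antibody adds. T cell transcripts did not differ by the test (median log2 fold change -0.15, 20 of 22 lower, adjusted p = 0.17), and Cd8a was at 16 ± 10.5 CPM in the combination and 15.7 ± 5.61 in circRNA (SD, n = 3). Inflammatory cytokines, macrophages, MHC class II and interferon gamma targets were lower in the combination, by medians of -0.49, -0.32, -0.45 and -0.37. Each had adjusted p = 0.521 with an estimated correlation, and without circRNA 2 and combination 1 the MHC class II (-0.16, adjusted p = 0.11) and interferon gamma (0.017, adjusted p = 0.552) calls ended. edgeR called 0 genes (lowest adjusted p = 0.851), with 847 at an unadjusted p below 0.05 where 757 are expected and mixed splits gave up to 1234. That number was 430 without circRNA 2, 443 without combination 1 and 266 without both. limma-voom called 0, and DESeq2 called 11, of which Naip1 was higher and 10 were lower. circRNA 2 and combination 1, the libraries with keratinocyte transcripts, are on opposite sides here. They had the highest T cell score of the circRNA group (0.999) and the lowest of the combination group (-0.394).

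In this comparison camera called lower inflammatory cytokines (23 of 26 lower, adjusted p = 3.34e-11) and macrophages and monocytes (22 of 24, adjusted p = 2.27e-14), both with adjusted p = 0.521 with an estimated correlation. It also called MHC class II (11 of 11, adjusted p = 1.42e-08), the interferon gamma response (27 of 27, adjusted p = 2.23e-09) and cytotoxic effectors (median -0.36, 19 of 21, adjusted p = 4.29e-05), each with adjusted p = 0.521 with an estimated correlation. MHC class I (-0.15, 19 of 21, adjusted p = 4.29e-05), dendritic cells (-0.35, 15 of 18, adjusted p = 0.000126) and NK cells (-0.34, 14 of 15, adjusted p = 0.000431) were called lower, each again with adjusted p = 0.521 with an estimated correlation. So were neutrophils (-0.59, 9 of 11, adjusted p = 0.00153), checkpoints (-0.3, 12 of 16, adjusted p = 0.00201), melanocytic cells (-0.32, 6 of 6, adjusted p = 0.0115) and regulatory T cells (-0.28, 8 of 10, adjusted p = 0.0301). These 4 too had adjusted p = 0.521 with an estimated correlation. Cell cycle genes were called higher (0.058, 21 of 28, adjusted p = 0.0168, adjusted p = 0.842 with an estimated correlation). Adjusted over the list alone, 4 cytokine and 2 macrophage genes passed and 0 genes of the other called lists, against 0 over all genes by edgeR or DESeq2. Tnf was at 4.98 ± 0.346 CPM against 8.64 ± 1.52 and Nfkbiz, an NF-kB target, at 17.1 ± 1.12 against 24.4 ± 1.61. The macrophage genes Itgam and Trem2 had log2 fold changes of -0.53 ± 0.13 and -0.47 ± 0.11. H2-DMa and H2-DMb1 had log2 fold changes of -0.44 ± 0.18 and -0.45 ± 0.19, and Nos2, which codes for inducible nitric oxide synthase, -1 ± 0.36. Gbp8 stood at -0.83 ± 0.28 and the chemokine gene Ccl5 at -1.01 ± 0.4. Nlrc5, a regulator of MHC class I, and H2-T23 stood at -0.51 ± 0.23 and -0.39 ± 0.17, and Ccl22 and Ccr7 at -0.88 ± 0.27 and -0.64 ± 0.24. Pdcd1lg2 was at 5.57 ± 4.08 CPM against 19.5 ± 15.5 and Cd274 at 84.1 ± 20 against 149 ± 71.4. Tnfrsf9 and Capg had log2 fold changes of -0.64 ± 0.26 and -0.3 ± 0.09, and Gzma and Klra8 -0.73 ± 0.4 and -1.22 ± 0.64. The neutrophil genes Mmp8 and Clec4d stood at -1.11 ± 0.43 and -1.3 ± 0.48, the melanocytic genes Mitf and Pmel at -0.43 ± 0.21 and -0.85 ± 0.45, and the mitotic genes Bub1 and Bub1b at 0.15 ± 0.08 and 0.16 ± 0.07 (edgeR adjusted p = 0.851 for these genes). Levels were low for Mmp8 (0.451 ± 0.206 against 0.967 ± 0.408 CPM), Pmel (0.959 ± 0.164 against 1.71 ± 1.24) and Klra8 (0.579 ± 0.255 against 1.34 ± 0.972).

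These differences leaned on circRNA 2 and on combination 1. Without circRNA 2, 6 of the 13 calls ended, among them NK cells (-0.17, adjusted p = 0.173), checkpoints (-0.075, 0.272) and regulatory T cells (-0.067, 0.461). The others were neutrophils (-0.17, 0.346), melanocytic cells (-0.14, 0.271) and cell cycle genes (0.037, 0.0508). Still called without it, the medians of inflammatory cytokines, MHC class II, dendritic cells and the interferon gamma response were -0.27, -0.27, -0.15 and -0.12. Without combination 1 the checkpoint (-0.18, 0.212) and melanocytic (-0.22, 0.0688) calls ended. The interferon gamma, MHC class I, dendritic cell and cell cycle medians without it were -0.22, -0.099, -0.2 and 0.1. Without both, chosen after seeing the data, 10 of the 13 calls ended. Those of inflammatory cytokines (-0.2), macrophages (-0.2) and cell cycle genes (0.085) were kept, each with adjusted p = 0.919 with an estimated correlation. With 4 calls gained, camera called 7 lists, 3 higher and 4 lower. Among these the T cell list was higher in the combination (median 0.46, adjusted p = 1.64e-11, adjusted p = 0.919 with an estimated correlation). Without combination 2 the regulatory T cell call ended (-0.24, 0.0846). Without combination 3 those of melanocytic cells (-0.39, 0.0685) and cell cycle genes (0.0079, 0.779) ended, with cytotoxic effectors at -0.61, regulatory T cells at -0.45 and T cells called lower (-0.63, 3.03e-07). The T cell list was also called lower without circRNA 1 (-0.27, 0.0228) or circRNA 3 (-0.29, 0.0061). Its median ran from -0.63 to 0.19 with 1 library left out. Without circRNA 3 the interferon gamma, checkpoint and melanocytic medians were -0.58, -0.47 and -0.48.

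Among lists not called in the combination against circRNA, the sign of the median, the mean and the test differed for the type I interferon response (median -0.0093, mean 0.014, test up, adjusted p = 0.652), fibroblasts and matrix (0.12, -0.052, up, 0.294) and endothelium (0.051, -0.04, down, 0.57). They differed also for keratinocytes (-0.21, -0.14, up, 0.991), adipocytes (-0.026, 0.085, down, 0.955) and p53 response (0.0064, -0.023, up, 0.904). RNA sensing (-0.011, adjusted p = 0.304), B and plasma cells (-0.18, 0.645), epithelial cells (-0.42, 0.462), erythroid cells (0.36, 0.645), hypoxia and glycolysis (-0.00092, 0.955), immediate early genes (-0.14, 0.125) and mitochondrial transcripts (-0.061, 0.462) were not called either, and skeletal muscle had a median of -0.61. Several of these were called without 1 library. The type I interferon list was called higher without circRNA 1 (0.12, adjusted p = 5.22e-08) or combination 1 (0.09, 0.000354) and lower without circRNA 3 (-0.15, 0.00327). Hypoxia was higher without circRNA 1 (0.12, 0.0143) and lower without circRNA 2 (-0.17, 2.27e-08), and fibroblasts were higher without circRNA 1 (0.28, 0.015) or combination 3 (0.2, 0.00462). Without circRNA 3, endothelium (-0.066, 0.00312), RNA sensing (-0.049, 0.00121) and immediate early genes (-0.2, 0.00169) were lower. Without circRNA 2, keratinocytes (6.32, 9.17e-06), adipocytes (5.31, 0.00609) and epithelial cells (0.32, 0.0375) were higher. Without combination 1, keratinocytes (-5.71, 0.000309), adipocytes (-4.2, 0.00154), epithelial cells (-0.82, 0.0261) and erythroid cells (-0.84, 0.0258) were lower, and without combination 2 keratinocytes were higher (0.42, 0.0402).

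Among the genes with the smallest p between the treated groups were Dpep2, which codes for a dipeptidase, at 14.4 ± 0.717 CPM against 24.2 ± 3.41, Sema3c, at 44 ± 3.95 against 68.5 ± 8.03, the X inactivation transcript Xist, at 75.6 ± 10.5 against 163 ± 52, Lilrb4b (-0.94 ± 0.19) and Oaf (-0.47 ± 0.09). Higher in the combination stood Naip1, which codes for an inflammasome receptor, at 9.37 ± 1.52 against 4.74 ± 1.11 CPM (log2 fold change 0.99 ± 0.2, DESeq2 adjusted p = 0.0128). Arsi, Plekha8, Plcg2 and Usp37 followed with log2 fold changes of 0.85 ± 0.2, 0.32 ± 0.08, 0.3 ± 0.08 and 0.29 ± 0.08. In the panel, Pdcd1 was at 8.39 ± 5.01 against 7.34 ± 2.76, Gzmb at 48.2 ± 6.46 against 72.7 ± 18.4, Ifng at 2.18 ± 0.588 against 4.54 ± 3.18 and Cxcl9 at 313 ± 65.7 against 423 ± 168. Isg15, Ddx58, Ifih1 and Eif2ak2 had log2 fold changes of 0.13 ± 0.23, 0.31 ± 0.17, 0.19 ± 0.15 and 0.22 ± 0.13, and the groups overlapped for all 10 panel genes (edgeR adjusted p = 0.851 to 0.996). Of all genes 920 lay apart upward and 787 downward, 11.3% where chance gives 10%. fry called 0 lists (lowest adjusted p = 0.568, mixed 0.465). Naip1 and Lilrb4b have close relatives in the genome, so their counts are uncertain.

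The fold changes of circRNA and of the combination, both against PBS, were related across 15132 genes, which are not independent replicates. Their Pearson r was 0.793 against 0.499 (0.442 to 0.537) in 20 simulations of unchanged groups that share the PBS libraries, and their covariance 0.145 against 0.0489, a difference of 0.0965. The sign was shared by 73.6% of genes against 66.8% in the simulations. Each treated group holds 1 library rich in keratinocyte RNA, which the simulations lack. They also draw each gene independently, so shifts that many genes share within a library are absent. Their range may thus be too narrow as a measure of chance. Without circRNA 2 and combination 1, chosen after seeing the data, the r was 0.625 against 0.399 (0.378 to 0.425) in 20 simulations of the other 7 libraries, and the covariance 0.0695 against 0.0341, a difference of 0.0355. edgeR called 0 genes in both comparisons. DESeq2 called 1 in both, Ccl2, where 20 simulations of unchanged groups that share the PBS libraries gave 0 to 5 (mean 1.4). The 3 PBS libraries do not give each comparison 2 of its own, so no value without shared controls was taken, and part of the excess over the simulations may come from the shared controls.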

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

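The alternatives that leave out circRNA 2 and combination 1, which are rich in keratinocyte RNA, with or without PBS 1, which is rich in fat cell RNA, were chosen after seeing the data. Of the alternative values for counts of genes, lists and shared genes, 122 stayed within 1.5 times the reported count or at 0 and 16 moved. edgeR's 0 genes in each comparison held under the other scaling factors, the stricter filter, the shorter count table, the compared groups alone, the robust spread, the fold threshold and limma-voom, and without each library in turn (0 to 0). DESeq2 gave 360 genes for circRNA against PBS, 2 for the combination against PBS and 11 for the combination against circRNA, with 1 gene shared between the first 2 comparisons. Without the filter 1 gene, Fgr, was called for circRNA against PBS. Without circRNA 2 and combination 1 edgeR called 1 gene, Ly6c2, for the combination against PBS, and also without PBS 1 it called 4 genes there and 8 for circRNA against PBS. The cause was not tested.

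Lists called numbered 17 to 20 for circRNA against PBS, 11 to 18 for the combination against PBS and 11 to 19 for the combination against circRNA when 1 library was left out. With an estimated correlation 0 lists were called in each comparison, and fry called 0 in each. For the combination against circRNA, 7 lists were called without the keratinocyte-rich libraries and 8 without the fat-rich one as well. Replicate numbers do not pair the samples (correlation of same-numbered libraries -0.443 to 0.12), and as a block they gave 0 genes in each comparison and 17, 18 and 13 lists.

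The direction of the list test turned, for lists called before or after, in 17 values, all in the combination against circRNA, and in 14 of them the median turned too. The cause was not tested. Without the keratinocyte-rich libraries, and then also without the fat-rich one, the medians were 0.461 and 0.475 for T cells, 0.0409 and 0.0528 for NK cells, 0.0244 and 0.0366 for checkpoints, 0.017 and 0.0286 for the interferon gamma response, and -0.729 and -0.717 for erythroid cells. Cytotoxic effectors stood at -0.186 without the keratinocyte-rich libraries, where only the direction of the test turned, as for the type I interferon response without circRNA 3 and keratinocytes without combination 1. With 1 library left out, medians ran from -0.145 to 0.117 for the type I interferon response, -0.842 to 0.323 for epithelial cells, -5.71 to 6.32 for keratinocytes, -4.2 to 5.31 for adipocytes, -0.844 to 0.833 for erythroid cells and -0.167 to 0.115 for hypoxia. Of the other alternative list values 1279 stayed on their side of the threshold, 149 lost and 77 gained a call, with a median of the other sign in 71, 1 and 7 of them. In all, the median had the other sign in 10 values for circRNA against PBS, 23 for the combination against PBS and 60 for the combination against circRNA. Named genes stayed on their side in 3091 of their alternative values, 32 of them with the other sign, and gained a call in 46, of which DESeq2 gave 44. Other scaling factors shifted the median gene by -0.0168 to 0.0172 log2. Of 55809 genes, 28809 had at least 1 count and 15132 passed the filter, so genes with few counts were not tested. How far depth or lack of expression accounts for this was not examined. Receptor segments were counted but not tested.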

Other observations

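Chosen only after the result was seen were the tests of skin, lymph node and tumor share, the test on keratinocyte genes, the permutation of the T cell score, and both tests of RNA passed between libraries, which replaced earlier versions after their outcome was known, that of combination 1 to circRNA 2 more than once. Variable segments of the T cell receptor beta chain, which only T cells rearrange, gave 43, 45 and 32 fragments in PBS 1, 2 and 3, or 1.74, 1.78 and 1.62 CPM of the library total. In circRNA 1, 2 and 3 they stood at 3.11 (exact interval 2.42 to 3.94), 6.62 (5.66 to 7.69) and 2.96 (2.29 to 3.77), and in combination 1, 2 and 3 at 1.14 (0.775 to 1.62), 2.95 (2.32 to 3.69) and 6.5 (5.55 to 7.56). Alpha chain segments stood at 1.61, 1.66 and 2.64 in PBS, 2.75, 4.19 and 3.86 in circRNA, and 2.02, 3.18 and 4.63 in the combination. Heavy chain segments of antibodies, which B and plasma cells express, gave 3, 1 and 6 fragments in PBS, 10, 44 and 15 in circRNA, and 7, 10 and 10 in the combination. Kappa chain segments gave 8, 5 and 20 in PBS, 22, 44 and 21 in circRNA, and 19, 11 and 21 in the combination. No test was run on these segments.

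The 6 libraries that received circRNA had T cell scores above all 3 PBS libraries and hypoxia scores below them. For these groups together edgeR called 0 genes (lowest adjusted p = 0.415), with 1733 genes at an unadjusted p below 0.05 (as many in 6 of 84 splits, highest other 2705), limma-voom called 0 and DESeq2 called 33, of which 28 were higher and 5 lower. With an estimated correlation 0 lists were called (lowest adjusted p = 0.296). With a real count of 0, all 84 splits of the 9 libraries into 6 and 3 give as many by construction, which says nothing about chance. Of these splits 8 gave any call, and the highest, with circRNA 1, circRNA 2 and combination 3 set apart, gave 176 genes, which points to a structure of the samples that was not tested further.

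The higher T cell and cytotoxic lists in circRNA than in PBS were weighed against other tissue and tumor share, and without the keratinocyte-rich libraries the T cell median was still 0.77, which argues against skin as the whole cause. Lymph node would bring B cells, and B cell genes, mostly Cd79b, gained 0.456 CPM (2.68 ± 0.324 against 2.22 ± 0.321, SD, n = 3) where CD3 genes gained 11.8 CPM (19.8 ± 7.4 against 8.05 ± 1.4), a ratio of 0.0387. It stays open, since that ratio reaches 0.0835 at 2 SE of the B cell gain, over the bound of 0.05. Heavy chain segments, not tested or scaled by library total, gave 10, 44 and 15 fragments in circRNA against 3, 1 and 6 in PBS. Kappa chain segments were less clear, at 22, 44 and 21 against 8, 5 and 20. If a lower share of tumor cells raised all other cells alike, endothelium would rise too, and its median was 0.0633 against 1.22 for T cells. Other cell types did not move alike, with macrophages at 0.44 and fibroblasts at -0.44. A changed tumor share is therefore not excluded. A link between circRNA and T cell RNA may still hold and stays open, since the score was higher in 6 of 6 treated libraries (difference 0.936, exact permutation p = 0.0476) but had an adjusted p = 0.242 over 28 lists. The smallest p that 84 splits can give is 0.012, so a single list could not pass that adjustment. Regulatory T cells (permutation p = 0.0238), cytotoxic effectors and mitochondrial transcripts (both 0.0357) had a smaller p and the same adjusted p. Combination 1 is the weakest case, with a T cell score of -0.394 against -0.504 in PBS 3. Its T cell receptor beta chain segments, at 1.14 CPM, were below PBS 1, 2 and 3 (1.74, 1.78 and 1.62 CPM). Those of the other treated libraries were above PBS.

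Keratinocyte and fat genes were high in circRNA 2 and combination 1. All 8 tested keratinocyte genes were higher in both than in each of the other 7 libraries, which restates the pattern, so skin carried along with the tumor stays open and untested. RNA of circRNA 2 passed to combination 1 would keep the ratios between genes, yet 7 of 32 keratinocyte, fat and muscle genes, such as Krt25, Krt71 and Acta1, lay under 0.25 of the median ratio of 0.756. RNA of combination 1 passed to circRNA 2 would need keratinocyte genes to reach 1.07 of their level in combination 1. Passed RNA at that level would make up all of circRNA 2. Yet the T cell scores of circRNA 2 and combination 1 were 0.999 and -0.394, which argues against it for these libraries. Of 10920 genes of at least 5 CPM in combination 1, 4, such as Cilp (29.8 against 197 CPM), lay under 0.25 of that ratio. This count also goes against it but is fewer than the 5 genes set as the bound. No biological explanation was tested.

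The number of genes called differed between tools in circRNA against PBS. edgeR's likelihood ratio test, which leaves out the uncertainty of each gene's spread, called 244 genes, 220 of them among the 360 of DESeq2, so that this uncertainty is a candidate explanation for the 0 of the quasi-likelihood test. That test had 4.21 prior and 6 residual degrees of freedom. The 10 splits of 6 libraries are too few for a share under 0.05. For circRNA against PBS, 1 of 10 splits gave as many genes by DESeq2 (real 360, highest other 319).

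For genes by edgeR the real count was 0 in each of the 3 comparisons, so 10 of 10 splits give as many by construction (highest other 0), which says nothing about chance. For lists the splits are too few for a share under 0.05, and 4 of 10 splits gave as many in circRNA against PBS (real 17, highest other 22), 3 of 10 in the combination against PBS (real 16, highest other 19) and 5 of 10 in the combination against circRNA (real 13, highest other 19). By DESeq2, a split of the combination and circRNA libraries gave 171 genes against the real 11, with circRNA 1, circRNA 2 and combination 3 on one side, and a split of the combination and PBS libraries gave 81 against 2, which points to a structure of the samples that was not tested further.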
